A study of Mus musculus with 17 samples.

How the data were processed

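Total RNA from mouse sciatic nerve was purified with a kit for lipid-rich tissue and made into libraries with a stranded total RNA kit, per the labels' protocols. The series text states that the replicates were independent biological samples. Reads were processed with CASAVA 1.8.2 and the genome build mm10, per the submitters' processing notes. The aligner, the counting program, the annotation release and the use of strand in counting are not given in the sources used here. Column names all carry the same sequencing lane, so lane and group are not confounded.

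The deposited table gives several measures per library. Counts of reads in the exons of each gene (total and uniquely placed) and in introns were made by the authors, per the file headers, and are whole numbers. RPKM values (exon reads scaled by exon length and library total) were also computed by the authors, per the file headers. A further signal column of the authors, named as expression values in the file headers, equals the RPKM times 1 factor per library, from 2.879 to 3.416, whose origin is not stated there. Exon lengths and gene coordinates come from the same table. RPKM and the scaled values served to recover library totals and to check the columns, and no test was run on them.

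The table used here ends inside the line of Gm24011, and the 18106 complete features before it were read. They are sorted by name, so genes later in the alphabet were not analysed here. For 5789 features no exon is annotated in the table, and these were not tested. Gene identifiers and symbols are those of the table, 18008 identifiers occur in GENCODE release M21, and coordinates are the table's own on mm10. Because only part of the genes is present, the library total of each sample was recovered from its exon reads, exon lengths and RPKM, with all genes of at least 100 reads agreeing within 1%. These totals set the CPM of each library. Intron reads made up 7.8 to 12.0% of the reads in the table. A count of 0 in a library allows a level of up to 0.163 to 0.25 CPM, taking 3 reads as the limit. Such limits and the counting intervals (95%, exact binomial) cover counting error only, since the libraries carry no molecular identifiers. Replicates of a group differed from each other by far more than sampling noise (chi-square per degree of freedom 10.22 to 93.46), so no library is a copy of another.

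Libraries were grouped by the genotype and operation in the labels into wild type and knockout sham, 1 day after transection and 14 days after crush. The replicate is the animal number. The groups, tests, gene lists and rule for naming genes were fixed before the data were examined. Total exon counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, which left 6028 genes, TMM factors, 1 coefficient per group over all 17 libraries, robust quasi-likelihood fits with 11 residual degrees of freedom, and Benjamini-Hochberg adjustment over all genes with a threshold of 0.05. All groups share 1 estimate of the spread, which the group of 2 needs. The 9 comparisons were knockout against wild type at each of the 3 conditions, each injury against sham in each genotype, and the genotype difference in each response. Levels are CPM on TMM-scaled totals, and log2 fold changes carry a prior count of 0.125. For genes with 0 reads in a group a lower bound of the fold was computed from 3 reads over the group, and for 1 to 3 reads the ratio of reads with its interval. RNA of skeletal muscle, fat, blood and other cells that adhere to a dissected nerve is counted with that of the nerve.

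Gene lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 21 lists with at least 3 tested members, and again with the correlation estimated per list. The lists were PRC2 subunits, CDK inhibitors, developmental transcription factors known as Polycomb targets, repair and immature Schwann cell genes, myelin, cholesterol synthesis, proliferation, chemokine and cytokine, interferon-stimulated, immediate early and extracellular matrix genes, and markers of macrophages, neutrophils, lymphocytes, mast cells, fibroblasts, endothelial, mural and fat cells and skeletal muscle. Hox and insulin-like growth factor genes had 0 tested members, perineurial and erythroid markers 1 each, and neuronal markers and sex-linked genes 2 each, too few for the set test.

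Named genes are Eed, the 10 largest rises and 10 largest falls of each comparison among called genes with a mean of at least 1 CPM and groups that did not overlap (no such rule for the genotype differences in response), leaving out predicted and clone-named genes, up to 4 members of each list with the smallest p in each comparison, and a fixed set of genes of interest. The text gives a selection of these.

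Alternatives fixed beforehand were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, at least 1 CPM in at least 3 samples, a fit of only the groups compared, each library left out in turn, the estimated correlation, and the animal as a block in the 1 day comparisons. Added after the data were seen were uniquely placed reads, library totals with no TMM factor, the presence of Ddx3y reads as a term, the level of Acta1 as a term, and fits without both libraries of wild type animal 1 or without the 6 libraries with Acta1 over 5 CPM.

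Sham and transected nerves that share a number came from the same animal, which pairs them. Their deviations from the group means correlated at 0.24 to 0.63 in the 6 pairs, all over 0.1, each animal correlated best with its own number, and reads of the Y-linked gene Ddx3y were present or absent alike in all 6. The design was nevertheless fixed without the block, and the blocked values stand beside the results they change.

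The tests were tried on simulated counts for the 6028 genes with 100 genes changed by 2-fold and 100 by 4-fold. For knockout against wild type, 50% and 81% were found in sham nerve, 52% and 80% at 1 day and 38% and 80% at 14 days. For transection against sham they were 63% and 83% in wild type and 49% and 90% in the knockout, and for crush against sham 57% and 88% in wild type and 50% and 79% in the knockout. For the genotype difference in response 26% and 70% were found at 1 day and 27% and 67% at 14 days. In the sham comparison 4 unchanged genes were called, and of 20 raised and 20 unchanged lists the set test called 20 and 0. The genes were simulated independently of each other, so this does not cover lists whose members vary together.

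Some genes share reads with others. Fewer than 50% of the exon reads were uniquely placed for 14 of the 112 named genes, among them Gfap (26.2%), Cxcl10 (33.2%), Ccl2 (29.6%), Fdps (23.8%), Dhcr24 (45.8%), Acta1 (40.9%), Alx4 (6.7%), Foxf1 (5.6%) and Cntf (0%), and their levels are uncertain. For 29 of the 112, another gene overlaps in the annotation. As the use of strand in counting is not known, reads of an overlapping antisense gene cannot be told apart from theirs.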

Results

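RNA was sequenced from the sciatic nerve of adult mice with and without Eed in Schwann cells, the glia that wrap peripheral axons. Eed is a core subunit of PRC2, the Polycomb complex that places a repressive mark on histones at silent developmental genes. The knockout animals carried a floxed Eed allele and a Cre recombinase under the Mpz promoter, which is active in Schwann cells. Nerves were taken distal to the lesion 1 day after transection or 14 days after a crush of 1 min, and sham nerves came from the other limb, which had a skin incision only. There were 17 libraries in 6 groups, with 3 animals in each group except the knockout 14 days after crush, which had 2. Sham and transected nerves came from the same animals, whereas the crushed nerves came from other animals, and the kind of injury and the time after it changed together. Library totals ran from 12009791 to 18421825 reads, and 28.2 to 31.9% of them fell on the genes available here. The gene table used here stopped in the alphabet at Gm24011, so later genes, among them Mpz, Mbp, Jun, Shh, Olig1 and the Hox clusters, were not analysed here.

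Eed itself was examined first. The gene (ENSMUSG00000030619, chromosome 7, 89954654 to 89980983, mm10) was expressed at 29.6 ± 1.33 CPM (exon counts scaled to the library total, mean and SD, n = 3) in wild type sham nerve and at 16.5 ± 1.23 CPM (n = 3) in knockout sham nerve. The log2 fold change was −0.84 ± 0.12 (SE; edgeR adjusted p = 3.8e-04), with all 3 knockout libraries below all 3 wild type libraries. Knockout nerve was also lower in every library 1 day after transection (25.5 ± 3.46 against 32.7 ± 3.9 CPM, n = 3 each) and 14 days after crush (22.2 ± 2.51, n = 2, against 30.4 ± 0.952 CPM, n = 3). These differences, −0.36 and −0.46 on the log2 scale, did not pass the edgeR test (adjusted p = 0.124 and 0.108), although DESeq2 called the 14 day difference at −0.48. Eed rose in knockout nerve from sham to 1 day (log2 fold change 0.63 ± 0.12, adjusted p = 0.00103), where wild type nerve gave 0.15 (adjusted p = 0.352). The difference between these responses did not pass its own test (0.48, adjusted p = 0.724). The counts cover the whole gene and not the deleted part, and the nerve also holds cells in which this Cre is not active.

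The first comparison asked which genes differed in nerve that had only a sham operation. Sham knockout nerve held transcripts of developmental genes that sham wild type nerve held at or near 0 reads. Alx1, a homeobox transcription factor of craniofacial development (ENSMUSG00000036602, chromosome 10, 102998707 to 103030215), stood at 13.4 ± 0.598 CPM (n = 3) in the knockout and at 0 reads in all 3 wild type libraries, which is at least 178-fold higher (against 3 reads over the group). Barx1, another homeobox gene, was at least 29.0-fold higher on the same basis. Ecel1, an endopeptidase known from injured neurons (ENSMUSG00000026247, chromosome 1, 87147655 to 87156521), reached 22.2 ± 4.32 CPM against 0.0256 ± 0.0443 CPM, a ratio of reads of 883 (95% counting interval 158 to 34890). Aqp4, the water channel of astrocytes, reached 17.7 ± 2.36 CPM with a ratio of 353 (97.3 to 2917). Of the 22 developmental transcription factors tested from a list of Polycomb targets, 11 rose over all genes (15 adjusted over the list alone) and 0 fell. The list had 81 members, of which 26 were in the gene table. A member silent in wild type passed the count filter only if another group expressed it, and it could not fall. In sham nerve 6 of the 22 had 0 reads in 1 group. The direction of this list is thus partly set by the filter, here and after injury.

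The cell cycle inhibitor locus on chromosome 4 was also higher in sham knockout nerve. Cdkn2a, which encodes p16 and p19 (ENSMUSG00000044303, 89274471 to 89294653), rose from 2.39 ± 0.0151 to 50.7 ± 1.58 CPM, a log2 fold change of 4.40 ± 0.28 (adjusted p = 3.08e-07). Its neighbour Cdkn2b, which encodes p15 (ENSMUSG00000073802, 89306289 to 89311032), rose from 8.41 ± 0.228 to 20.8 ± 0.81 CPM (1.30 ± 0.20, adjusted p = 7.95e-04). Of the 7 CDK inhibitors tested, these 2 rose and Cdkn1b, which encodes p27, fell by 0.92 on the log2 scale, with 3 higher and 1 lower when adjusted over the list alone. The Cdkn1b call was lost without wild type animal 7 or 14 or any of the 3 knockout animals (adjusted p 0.0726 to 0.127).

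Some genes of injured or immature Schwann cells were already higher in sham nerve, taken from animals with a transection in the other limb. Gfap, an intermediate filament of immature and repair Schwann cells (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), stood at 167 ± 12.1 CPM against 7.06 ± 3.42 CPM (log2 fold change 4.56 ± 0.36, adjusted p = 2.12e-06). Fabp7, a fatty acid binding protein of immature Schwann cells, stood at 38.8 ± 4.55 against 0.866 ± 0.35 CPM (5.48 ± 0.41). Atf3, a transcription factor induced by injury, was lower in the knockout, at 7.43 ± 0.682 against 35.0 ± 5.28 CPM (−2.24 ± 0.27, adjusted p = 8.51e-05). Of 11 repair Schwann cell genes, Gfap and Gdnf rose and Atf3 fell (5 rose and 1 fell adjusted over the list alone), and of 6 immature Schwann cell genes Gfap and Fabp7 rose (2 adjusted over the list alone). The Gdnf call (2.46 ± 0.66, adjusted p = 0.0296) was lost without wild type animal 7, 14 or 1 or knockout animal 6 (adjusted p 0.0556 to 0.139). Other genes that fell were Adgb, an androglobin gene (−3.12), Ctnna2, an adhesion gene (−1.98), and B3gnt5, a glycolipid synthase gene (−1.81). Of 12 myelin genes 1 fell, the dystrophin-related Drp2 (−0.91 ± 0.23, adjusted p = 0.0277; 1 rose and 3 fell adjusted over the list alone), and its call was lost without wild type animal 7 or 14 or any of the 3 knockout animals (adjusted p 0.0571 to 0.148).

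In all, 418 of 6028 genes differed between knockout and wild type sham nerve by edgeR's quasi-likelihood test (319 higher and 99 lower, of which 237 and 44 by at least 2-fold). The lower count depended on single libraries and on the model: it was 164 (with 364 higher) by DESeq2 and 21 (with 146 higher) with the Acta1 level as a term. It was 220 (with 346 higher) without wild type sham 1, which stood apart from the other sham nerves, and 250 without both libraries of that animal. It was 47 without wild type sham 7, 57 without 14, and 48, 53 and 51 without knockout sham 15, 17 and 6. The developmental list moved up as a set (camera adjusted p = 3.11e-16, and 0.0205 with an estimated correlation), and none of the other 20 lists passed. The count filter, which favours a rise for members silent in wild type, bears on this set result too. The level of skeletal muscle RNA varied between libraries, though no muscle marker was called (0 of 4 by edgeR, camera adjusted p = 0.931; 1 rose and 3 fell adjusted over the list alone): Acta1, muscle actin, stood at 15.8 ± 14.8 CPM in wild type (31.1, 14.7 and 1.64 CPM) and 0.216 ± 0.204 CPM in knockout sham nerve (adjusted p = 0.0571). With the Acta1 level in the model the count in all was 167, and without the 6 libraries over 5 CPM of Acta1 it was 168, both chosen after the data were seen.

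**Figure D1:**
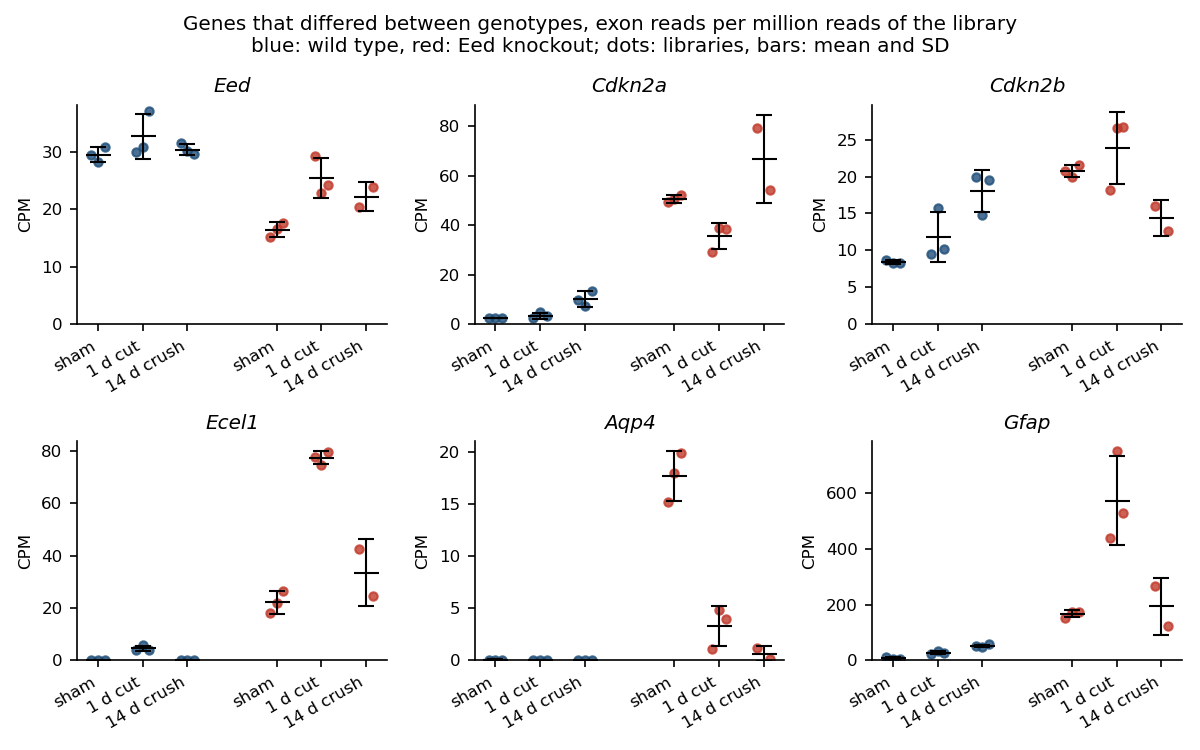
CPM of genes that differ between Eed knockout and wild type nerve, per library, in sham nerve, 1 day after transection and 14 days after crush. Points are libraries and bars are group means with SD (n = 3 per group, and 2 for the knockout 14 days after crush). Cdkn2a is higher in knockout nerve at all 3 times.

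The second comparison asked how knockout and wild type nerve differed 1 day after transection. The developmental genes were again higher. Alx1 stood at 7.14 ± 0.71 CPM against 0.0184 ± 0.0319 CPM, a ratio of reads of 338 (95% counting interval 60.3 to 13390), and Gata4 and Barx1 were at least 31.4-fold and 18.3-fold higher than a wild type group at 0 reads. Of the 22 developmental transcription factors 9 rose (13 adjusted over the list alone). Cdkn2a reached 35.5 ± 5.36 against 3.36 ± 1.19 CPM (log2 fold change 3.41 ± 0.26, adjusted p = 2.66e-06), and Cdkn2b was higher by 1.02 ± 0.20 (adjusted p = 0.00809). These were 2 of the 7 CDK inhibitors (2 higher and 1 lower adjusted over the list alone).

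Some genes of the repair Schwann cell, the state that denervated Schwann cells adopt, were higher in the transected knockout nerve, 4 of the 11 tested. Gfap stood at 571 ± 160 against 27.5 ± 4.82 CPM (log2 fold change 4.38 ± 0.35, adjusted p = 3.57e-06). Fgf5, a fibroblast growth factor (ENSMUSG00000029337, chromosome 5, 98254184 to 98277030), stood at 16.8 ± 2.86 against 4.67 ± 1.56 CPM (1.85 ± 0.26, adjusted p = 5.8e-04). The growth-associated gene Gap43 (1.76 ± 0.29) and the neurotrophic factor gene Artn (3.30 ± 0.58) rose too, while Gdnf, another neurotrophic factor, was at 56.7 ± 17.7 and 52.3 ± 16.7 CPM (0.12 ± 0.31, adjusted p = 0.925). Adjusted over the repair list alone 5 rose, and 3 of 6 immature Schwann cell genes rose, namely Gfap, Gap43 and Fabp7 (3 adjusted over the list alone). The chemokine gene Cxcl10 rose by 1.70. Lower in the knockout were B3gnt5 (−1.98), the collectin gene Colec11 (−1.98) and Aldh1a1, an enzyme of retinoic acid synthesis (−1.39).

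At 1 day 231 genes differed (191 higher and 40 lower, of which 148 and 23 by at least 2-fold). Leaving out 1 library gave from 154 (wild type transected 1) to 241 (wild type transected 14) genes in all. The lower count moved both ways: it was 70 by DESeq2 and 63 without both libraries of wild type animal 1, 19 without wild type transected 7, 15 without knockout transected 15, 20 without knockout transected 6 and 19 with the Acta1 level as a term. The developmental (camera adjusted p = 2.92e-13), repair (4.67e-05) and immature (1.94e-05) lists moved up as sets. When the correlation was estimated, the adjusted p was 0.0431 for the developmental, 0.322 for the repair and 0.205 for the immature list. The 5 adipocyte markers moved down as a set with 0 members called (adjusted p = 0.0143, and 0.819 with an estimated correlation). Acta1 stood at 15.3 ± 19.9 CPM in knockout and 0.569 ± 0.43 CPM in wild type transected nerve. A fit of these 6 libraries alone called 75 genes (73 higher and 2 lower), and leaving out the 6 libraries with Acta1 over 5 CPM gave 106 (102 and 4).

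The third comparison asked whether the genotypes still differed 14 days after crush. Developmental genes remained higher in the knockout: Alx1 by at least 90.8-fold, Barx1 by at least 64.8-fold and the homeobox gene En2 by at least 33.1-fold, each against 0 reads in wild type. Ecel1 was higher by 7.40 ± 0.41 on the log2 scale. Of the 22 developmental transcription factors 6 rose (11 adjusted over the list alone). Cdkn2a stood at 66.8 ± 17.9 CPM (n = 2) against 10.1 ± 3.1 CPM (n = 3), a log2 fold change of 2.73 ± 0.26 (adjusted p = 5.07e-05), and was the 1 member called of the 7 CDK inhibitors (1 adjusted over the list alone). Cdkn2b stood at 14.4 ± 2.39 against 18.1 ± 2.89 CPM (−0.33 ± 0.22, adjusted p = 0.58).

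Some repair genes were lower in the knockout, of which Atf3 had already been lower in sham nerve. Fgf5 stood at 5.21 ± 1.65 CPM (n = 2) against 25.4 ± 3.59 CPM (n = 3), a log2 fold change of −2.28 ± 0.30 (adjusted p = 9.23e-04), and its call held without any 1 of the 5 libraries. The epidermal growth factor family gene Btc (−1.43 ± 0.31, adjusted p = 0.0301) and Atf3 (−1.17 ± 0.28, adjusted p = 0.0476) fell as well, while Gfap was still higher (1.89 ± 0.33, adjusted p = 0.00688). Thus 1 of 11 repair genes rose and 3 fell (1 and 4 adjusted over the list alone). Of 6 immature Schwann cell genes Gfap and Fabp7 rose (3 adjusted over the list alone). The Gfap call was lost without knockout animal 22 (1.19, adjusted p = 0.188). The Btc call was lost without wild type animal 23 or 21 or knockout animal 22 or 24 (adjusted p 0.0736 to 0.32), the Atf3 call without any 1 of the 5 animals (0.0596 to 0.396) and the Fabp7 call without wild type animal 23 or 21 or knockout animal 22 (0.0504 to 0.239).

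Genes of myelin lipid synthesis lay on the lower side in knockout nerve 14 days after crush. Of the 8 cholesterol synthesis genes, Fdps (−1.16 ± 0.26, adjusted p = 0.0306) and Cyp51 (−1.01 ± 0.22, adjusted p = 0.0301) fell (4 adjusted over the list alone). Of 12 myelin genes, Aspa, the aspartoacylase gene, fell (−1 ± 0.23, adjusted p = 0.041; 3 adjusted over the list alone), and Cnp (−0.91, adjusted p = 0.171) and the connexin gene Gjb1 (−1.05, adjusted p = 0.124) did not pass. The Aspa call was lost without any 1 of the 5 animals (adjusted p 0.0776 to 0.334), and those of Fdps and Cyp51 without any 1 of wild type 21 and 26 and knockout 22 and 24 (0.0916 to 0.276). None of the 6 endothelial markers was called (2 higher adjusted over the list alone), and the highest was Flt1, a vascular endothelial growth factor receptor gene (0.89, adjusted p = 0.164). Cntf, a neurotrophic factor gene whose reads were never uniquely placed, was at −3.08 (adjusted p = 0.00503, and 0.0845 and 0.0793 without knockout animal 22 or 24).

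At 14 days 129 genes differed (98 higher and 31 lower, of which 79 and 21 by at least 2-fold), and DESeq2 called 265 (150 higher and 115 lower). The developmental list moved up as a set (camera adjusted p = 1.59e-11), as did the endothelial list (0.00104), and the repair (0.00448), myelin (3e-07) and cholesterol (1.41e-04) lists moved down. Estimating the correlation per list, the adjusted p was 0.0719 for the developmental, 0.481 for the endothelial, 0.539 for the repair, 0.481 for the myelin and 0.291 for the cholesterol list, so none of the 5 calls held. The shift of the repair list lay mostly in 1 knockout animal. Its score (mean log2 CPM of the members less their mean over all libraries) was 0.28 in knockout 24 and 1.10 in knockout 22. Wild type 23, 21 and 26 had 1.18, 1.12 and 1.26. Without knockout animal 22 or 24 the count of genes was 20 (3 of them lower) or 64 (5 lower), and without wild type animal 23, 21 or 26 it was 72, 80 or 77. Acta1 stood at 18.3 ± 15.8 CPM in wild type and 0.0975 ± 0.138 CPM in knockout nerve at 14 days. The count was 39 with the Acta1 level in the model, 18 without the 6 libraries with Acta1 over 5 CPM, and 228 in a fit of these 5 libraries alone.

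**Figure D2:**
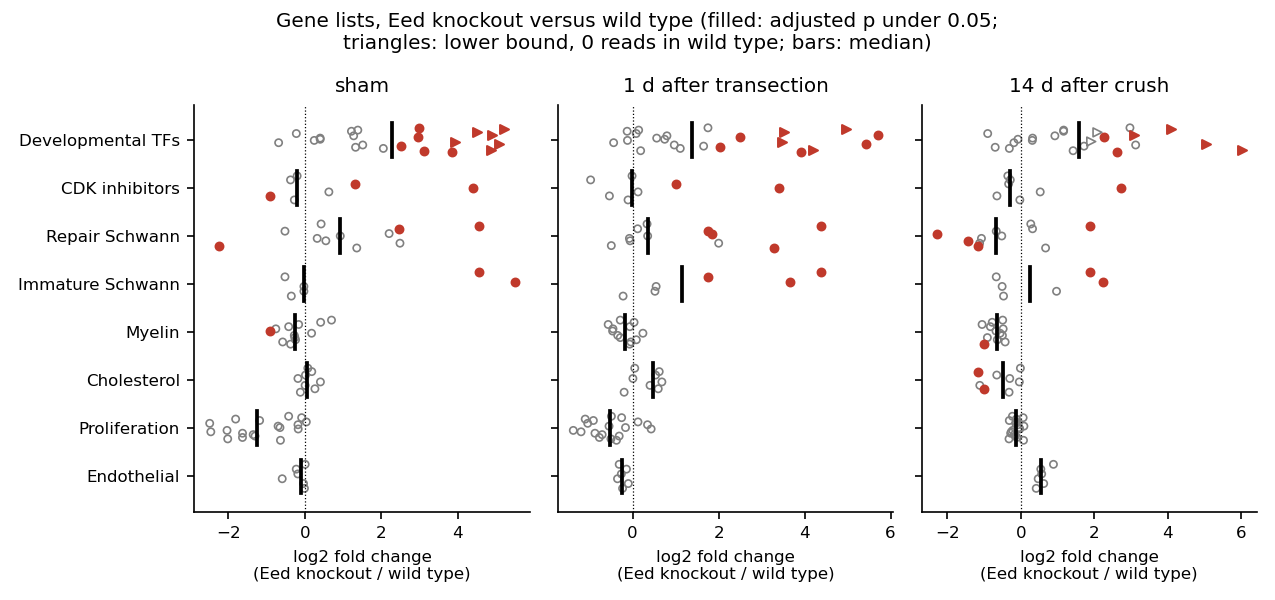
Log2 fold changes, knockout over wild type, of the tested members of 8 gene lists in sham nerve, 1 day after transection and 14 days after crush. Filled points passed an adjusted p of 0.05 over all genes, triangles stand at the lower bound for genes with 0 reads in wild type, and bars are list medians. The developmental transcription factors lie mostly above 0 at all 3 times, and the myelin and cholesterol genes lie below 0 at 14 days.

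The calls of the 3 genotype comparisons were then compared with each other. Sham and 1 day shared 142 higher and 21 lower genes, where independent lists of those sizes would share 10.1 and 0.7. Sham and 14 days shared 76 and 8 (5.2 and 0.5 for independent lists), and 1 day and 14 days shared 59 and 2 (3.1 and 0.2). Added over both directions, the overlaps with 14 days (84 and 61 genes) were both 16 without knockout crush 22. With the Acta1 level as a term they were 27 and 26, and without the 6 libraries with Acta1 over 5 CPM both were 14. For sham and 14 days leaving out knockout crush 24 or wild type crush 23, 21 or 26 gave 52, 51, 52 or 53, and DESeq2 gave 128. The fits of only the groups compared gave 37 for 1 and 14 days and 56 for sham and 1 day (163), for which the Acta1 term gave 94 and leaving out the 6 libraries 71. In all 3 comparisons 58 genes were higher, among them Alx1, Alx4, Barx1, Cdkn2a, Ecel1, En2, Fabp7 and the cyclin gene Ccnd1, and 2 were lower, B3gnt5 and A330069K06Rik (Ccnd1 and A330069K06Rik were named after their values were seen). Fgf5 was called in opposite directions at 1 and 14 days, and Gm10561 in sham and at 14 days. The comparisons share no library, but sham and transected nerves came from the same animals, so part of the excess between sham and 1 day may come from the animals.

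The response to transection was examined within each genotype, beginning with wild type. After 1 day the neurotrophic factor gene Gdnf (ENSMUSG00000022144, chromosome 15, 7811011 to 7837575) rose from 0.172 ± 0.0994 to 52.3 ± 16.7 CPM (n = 3 each), a log2 fold change of 8.15 ± 0.52 (adjusted p = 2.73e-07). Fgf5 rose from 0.0504 ± 0.0441 to 4.67 ± 1.56 CPM, a ratio of reads of 90.8 (95% counting interval 24.8 to 754), and the cytokine genes Clcf1 and Crlf1 rose by 4.92 and 3.74. Of 11 repair genes 7 rose (9 adjusted over the list alone). Chemokine and cytokine genes rose in 14 of 17 cases (14 adjusted over the list alone), among them Ccl2, which attracts monocytes (4.93), and the neutrophil attractants Cxcl5 (8.26) and Cxcl2 (6.78). Of 8 immediate early genes 6 rose (7 adjusted over the list alone), such as Egr1 (3.77) and Fosl1 (3.63). The neutrophil receptor genes Cxcr2 (5.61) and Csf3r (3.56) rose, and the neutrophil markers counted 2 of 3 higher (3 adjusted over the list alone).

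Myelin and lipid genes went the other way in transected wild type nerve. Of 12 myelin genes 8 fell and 2 rose (9 and 2 adjusted over the list alone), with Fa2h, which hydroxylates myelin lipids, at −1.93, Cnp at −1.64 and the claudin gene Cldn19 at −1.50. Of 8 cholesterol synthesis genes 6 fell (6 adjusted over the list alone), led by Dhcr24 (−1.93), Fdft1 (−1.23) and Fdps (−1.20). The Schwann cell adhesion genes Cdh2 (−2.06) and Cdh19 (−1.29) and the neuregulin receptor gene Erbb3 (−1.34) fell. These were 3 of the 6 immature Schwann cell genes, of which 1 other, Gfap, rose (1 and 3 adjusted over the list alone).

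In wild type 2039 genes changed 1 day after transection (907 higher and 1132 lower, of which 366 and 435 by at least 2-fold). Which direction held the majority depended on the scaling and the block: it was 1092 higher and 918 lower with library totals and no TMM factor, and 1200 and 1193 with the animal as a block. The chemokine (camera adjusted p = 5.69e-09), immediate early (6.38e-07), repair (6.47e-06), macrophage (0.0259) and proliferation (0.0314) lists moved up, and the cholesterol (0.00743) and myelin (0.0259) lists down. With an estimated correlation none of the 7 held (adjusted p = 0.206 for the chemokine, 0.079 for the immediate early, 0.221 for the repair, 0.444 for the cholesterol and 0.853 for the macrophage, proliferation and myelin lists). Of 12 macrophage markers 1 rose, Cd14 (0 adjusted over the list alone), and of 18 proliferation genes 2 rose (2 adjusted over the list alone). The Cd14 call was lost without wild type sham 7 (edgeR adjusted p = 0.158) or 14 (0.163) or transected 14 (0.0698) or 1 (0.163). Wild type sham animal 1 held Cd68, a macrophage gene, at 114 CPM, against 11.8 CPM in animal 7 and 11.6 CPM in animal 14. With the animal as a block the 3 neutrophil markers also moved up as a set (adjusted p = 0.0362, and 0.55 with the correlation estimated). The count of genes was 1299 without wild type sham animal 7, 1287 without sham animal 14 and 1302 without transected animal 1. It was 760 in a fit of these 6 libraries alone and 285 without the 6 libraries with Acta1 over 5 CPM.

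Knockout nerve also responded to transection. Gdnf rose by 5.81 ± 0.41 and Fgf5 by 5.97 ± 0.35 on the log2 scale, from 1.00 ± 0.55 to 56.7 ± 17.7 CPM and from 0.262 ± 0.0436 to 16.8 ± 2.86 CPM. All 11 repair genes rose (11 adjusted over the list alone), with Gap43 at 1.72 and Clcf1 at 4.53. Of 17 chemokine and cytokine genes 15 rose (15 adjusted over the list alone), of 8 immediate early genes 8 rose (8 adjusted over the list alone), and of 3 neutrophil markers 3 rose (3 adjusted over the list alone), with Cxcr2 at 8.38 and Csf3r at 5.15. Acod1, an enzyme gene of activated macrophages, was at least 142-fold higher than a sham group at 0 reads. Of 12 myelin genes 6 fell (6 fell and 1 rose adjusted over the list alone), including Gjc3, a connexin gene (−1.75), Cnp (−1.66) and Fa2h (−1.57), and of 8 cholesterol synthesis genes 5 fell (6 adjusted over the list alone), Dhcr24 by 1.53 (log2 fold change −1.53). Fabp7 (−2.48) and the adrenergic receptor gene Adra2c (−3.74) fell from their raised sham levels.

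In the knockout 2555 genes changed 1 day after transection (1235 higher and 1320 lower, of which 537 and 595 by at least 2-fold, but 1304 and 1217 with no TMM factor and 1507 and 1349 with the animal as a block). Leaving out 1 library gave from 1799 (knockout transected 15) to 2520 (knockout transected 17) genes in all. The repair (camera adjusted p = 5.45e-08), chemokine (2.32e-08), immediate early (2.31e-07) and proliferation (0.0207) lists moved up. With an estimated correlation the adjusted p was 0.145 for the repair, 0.201 for the chemokine, 0.0811 for the immediate early and 0.853 for the proliferation list. Of 18 proliferation genes 6 rose (6 adjusted over the list alone). With the animal as a block the myelin list moved down (adjusted p = 0.035) and the macrophage list up (0.00762), against 0.0706 for both without it, and neither passed with the correlation estimated (0.707 and 0.685). Of 12 macrophage markers 4 rose (4 adjusted over the list alone), Fcgr1 by 3.08. Acta1 rose from 0.216 ± 0.204 to 15.3 ± 19.9 CPM (6.07 ± 1.81, adjusted p = 0.0148), a call lost without sham animal 15 (adjusted p = 0.0637) or transected animal 15 (0.0874). In wild type it had moved the opposite way after transection, from 15.8 ± 14.8 to 0.569 ± 0.43 CPM (−4.72 ± 1.59, adjusted p = 0.0335), a call lost without sham 7 (0.115) or 14 (0.062) or transected 7 (0.0595), 14 (0.0864) or 1 (0.104). The difference between the genotypes in this response did not pass (10.79 ± 2.41, adjusted p = 0.217). The count of genes was 1646 with the Acta1 level in the model and 777 without the 6 libraries with Acta1 over 5 CPM.

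The genotype difference in the response to transection was tested directly. Of 6028 genes 1 passed, Ecel1, at −5.30 ± 0.80 on the log2 scale (adjusted p = 0.0259): it went from 0.0256 ± 0.0443 to 4.60 ± 1.08 CPM in wild type and from 22.2 ± 4.32 to 77.3 ± 2.47 CPM in the knockout, so both rose and the wild type rose by the larger ratio. Wild type sham nerve lay near 0 reads of Ecel1, so the sizes of that ratio and of the difference are uncertain. Without wild type sham 7 or 14 the difference was −7.33 or −4.78. In CPM the knockout rose by more. The call was lost in 7 of the 12 fits that left out 1 library, namely wild type sham 7 (adjusted p = 0.106) and 14 (0.144), knockout sham 17 (0.0677) and 6 (0.0632), and transected knockout 15 (0.0754), 17 (0.078) and 6 (0.0748). At an unadjusted p under 0.05 there were 289 genes, DESeq2 called 20, and the fit with the animal as a block called 2. No list passed, but with the animal as a block 4 did: developmental genes (down, adjusted p = 0.0109), proliferation genes (up, 0.0319), adipocyte markers (down, 0.0362) and skeletal muscle markers (up, 1.34e-05). None of these 4 held in the blocked fit with the correlation estimated (adjusted p = 0.68 for the first 3 and 0.188 for the last). Of 100 simulated genes changed by 2-fold and 100 by 4-fold, 26% and 70% were found in this comparison, and smaller changes were not simulated.

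**Figure D3:**
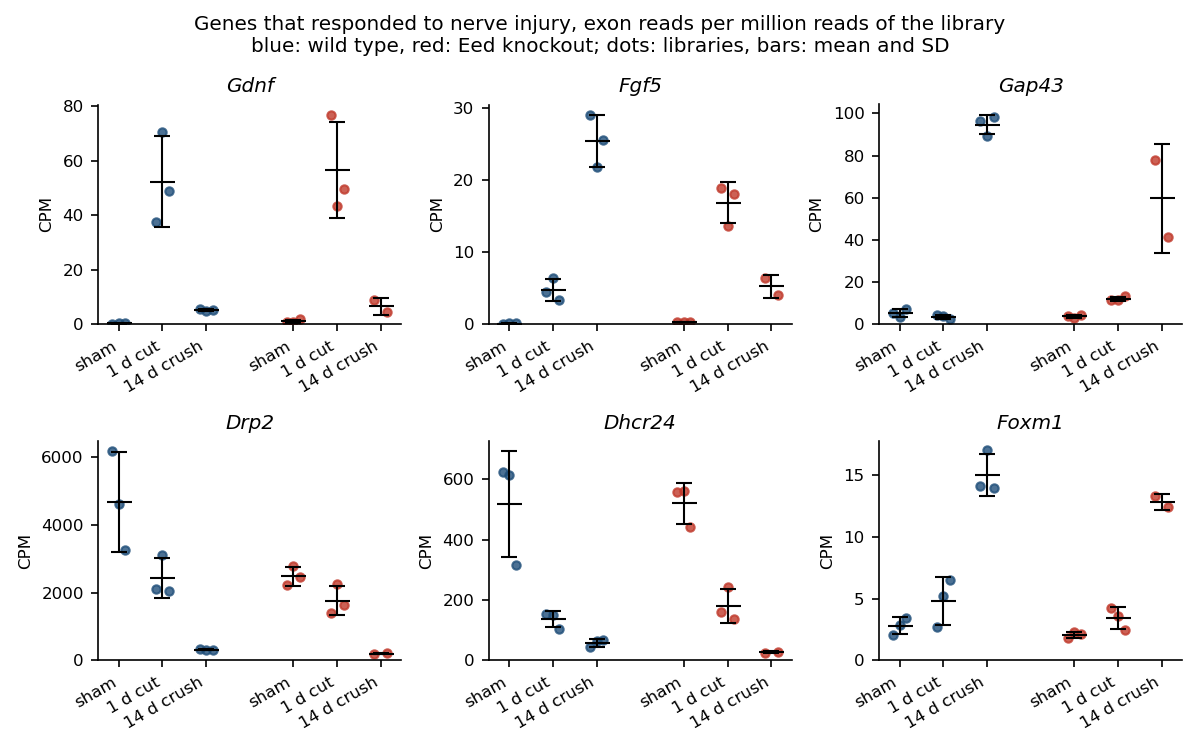
CPM of genes that respond to injury, per library, in wild type and Eed knockout nerve, for sham nerve, 1 day after transection and 14 days after crush. Points are libraries and bars are group means with SD (n = 3 per group, and 2 for the knockout 14 days after crush). Gdnf is highest 1 day after transection and Drp2 is lowest 14 days after crush in both genotypes.

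The later response was examined 14 days after crush, first in wild type. The crushed animals had no sham library of their own. Crushed nerves of both genotypes were therefore set against the sham nerves of the transected animals. Fgf5 rose from 0.0504 ± 0.0441 to 25.4 ± 3.59 CPM (n = 3 each), a ratio of reads of 509 (95% counting interval 141 to 4210). Gap43 (ENSMUSG00000047261, chromosome 16, 42248442 to 42340651) rose from 5.20 ± 1.96 to 94.8 ± 4.66 CPM (log2 fold change 4.19 ± 0.30, adjusted p = 4.34e-07), and Btc (4.83) and Gdnf (4.82) rose alongside. Of 11 repair genes 10 rose (10 adjusted over the list alone). Of 18 proliferation genes 14 rose (14 adjusted over the list alone), such as the transcription factor gene Foxm1 (2.42) and Cdc20 of the anaphase complex (1.60). Cdkn2a rose from 2.39 ± 0.0151 to 10.1 ± 3.1 CPM (2.07 ± 0.27, adjusted p = 4.5e-05) and Cdkn2b by 1.10. Of 17 chemokine and cytokine genes 9 rose (9 adjusted over the list alone), with Cxcl10 at 3.79.

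Drp2, which links the myelinating Schwann cell to its basal lamina (ENSMUSG00000000223, chromosome X, 134404551 to 134456573), fell from 4675 ± 1470 to 319 ± 22.8 CPM (−3.88 ± 0.26, adjusted p = 3.43e-07). Fa2h (−1.91) and Gjb1 (−1.29) fell as well, and of 12 myelin genes 5 fell and 2 rose (5 and 2 adjusted over the list alone). Of 8 cholesterol synthesis genes 6 fell (6 adjusted over the list alone), Dhcr24 with a log2 fold change of −3.16 and Fdft1 likewise (−1.77). The largest fall was that of Etnppl, an enzyme gene of phospholipid breakdown, from 149 ± 59.9 to 0.0686 ± 0.0701 CPM, a ratio of reads of 2079 (95% counting interval 711 to 10080).

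In wild type 2412 genes changed 14 days after crush (1185 higher and 1227 lower, of which 490 and 573 by at least 2-fold). The repair (camera adjusted p = 3.79e-07), proliferation (2.76e-06) and chemokine (0.00664) lists moved up and the cholesterol list down (0.00224). With an estimated correlation the adjusted p was 0.341 for the repair, 0.795 for the proliferation, 0.795 for the chemokine and 0.587 for the cholesterol list. With library totals and no TMM factor the split was 1694 higher and 869 lower, and the median of all genes went from −0.022 to 0.152, so changes here are relative to the bulk of the genes. Without the 6 libraries with Acta1 over 5 CPM the count was 310.

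Knockout nerve 14 days after crush showed Gap43 higher by 4.05 ± 0.32, Fgf5 by 4.28 ± 0.37, Btc by 2.86, Gdnf by 2.68 and Atf3 by 2.65 on the log2 scale. In all 8 of 11 repair genes rose (8 adjusted over the list alone). All 18 proliferation genes rose (18 adjusted over the list alone), with Cdk1 at 5.36, and of 17 chemokine and cytokine genes 9 rose (10 adjusted over the list alone). Knockout over wild type, the proliferation genes had a median log2 fold change of −1.24 in sham nerve and −0.13 at 14 days. The sham difference came mostly from wild type animal 1. Its list score (mean log2 CPM of the members less their mean over all libraries) was 0.42. Wild type sham 7 and 14 had −1.51 and −1.11, and knockout sham 15, 17 and 6 had −1.43, −1.57 and −1.38. Wild type sham 1 also enters the comparison of crush against sham in wild type. Of 8 immediate early genes 5 rose (6 adjusted over the list alone) and of 4 interferon-stimulated genes 3 rose (3 adjusted over the list alone). Of 12 myelin genes 7 fell (7 adjusted over the list alone), with Drp2 at −3.64, Fa2h at −2.31 and Gjb1 at −2.18, and of 8 cholesterol synthesis genes 6 fell (7 adjusted over the list alone), with Dhcr24 at −4.28 and Fdps at −2.62. Aqp4 (−4.72) and Fabp7 (−3.06) fell from their raised sham levels. Cdkn2a was at 50.7 ± 1.58 CPM in sham (n = 3) and 66.8 ± 17.9 CPM (n = 2) at 14 days (0.40 ± 0.25, adjusted p = 0.248).

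In the knockout 1798 genes changed 14 days after crush (880 higher and 918 lower, of which 431 and 498 by at least 2-fold). The repair (camera adjusted p = 3.11e-05), proliferation (1.63e-08), chemokine (4.16e-04), immediate early (3.72e-04) and interferon (0.0342) lists moved up, and the cholesterol (8.33e-06) and myelin (2.56e-04) lists down. With an estimated correlation none of the 7 held (adjusted p = 0.325 for the repair, 0.52 for the proliferation and chemokine, 0.222 for the immediate early and cholesterol and 0.581 for the interferon and myelin lists). With library totals and no TMM factor the split was 1310 higher and 712 lower, and the median of all genes went from 0.025 to 0.183. The count was 916 without knockout animal 22, 1010 without animal 24 and 2783 in a fit of these 5 libraries alone.

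The genotype difference in the response to crush was called for 25 genes (3 higher and 22 lower), with 563 at an unadjusted p under 0.05 and 96 by DESeq2. Cspg5, a neural chondroitin sulfate proteoglycan (−4.87 ± 0.50, adjusted p = 6.01e-04), Galnt3, a glycosyltransferase (−4.21 ± 0.46, adjusted p = 6.01e-04), and the cadherin gene Cdh10 (−3.06 ± 0.36, adjusted p = 0.001) were called in all 11 fits that left out 1 library. Cspg5 rose from 1.64 ± 0.784 to 12.2 ± 2.45 CPM in wild type and went from 30.2 ± 7.98 to 7.56 ± 0.343 CPM in the knockout. Fgf5 (−4.49 ± 0.76, adjusted p = 0.0218) and Cdkn2b (−1.63 ± 0.30, adjusted p = 0.0263) were also called, and Cdkn2a (−1.67 ± 0.37, adjusted p = 0.0729) was not. The Fgf5 call was lost without wild type crush animal 26, knockout sham 15, 17 or 6 or knockout crush animal 24 (adjusted p 0.0512 to 0.0604). The Cdkn2b call was lost in 9 of the 11 fits, all but those without wild type sham 1 and wild type crush 21 (adjusted p 0.0555 to 0.236).

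Among the lists, 2 of 11 repair genes had a lower response in the knockout (1 higher and 7 lower adjusted over the list alone), as had 2 of 6 immature Schwann cell genes (1 higher and 2 lower), 0 of 8 cholesterol genes (3 lower), 0 of 12 myelin genes (0) and 0 of 22 developmental genes (0), while 0 of 6 endothelial markers had a higher one (1), the second value in each case adjusted over the list alone. As sets the repair (camera adjusted p = 3.02e-05), cholesterol (4.43e-04), myelin (0.00795), developmental (0.0281) and immature (0.0294) lists moved down and the endothelial list up (2.23e-04). With an estimated correlation the adjusted p was 0.385 for the repair and cholesterol, 0.698 for the myelin, 0.647 for the developmental and immature and 0.407 for the endothelial list. The count of genes was 15 without wild type sham 7, 13 without sham 14, 10 without wild type crush 21, 7 without knockout sham 17, and 5 without wild type crush 26, knockout sham 15 or 6 or knockout crush 24. It was 58 without both libraries of wild type animal 1, 48 with only the groups compared, 39 with Ddx3y reads as a term and 4 without the 6 libraries with Acta1 over 5 CPM.

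Last, the genes that changed 1 day after transection in wild type were followed in the comparison of the genotypes 14 days after crush, which uses none of the same libraries. The 907 genes called up had a median log2 fold change of −0.015 between genotypes, and the set did not stand apart from other genes by camera of limma (adjusted p = 0.663). Among them 16 were higher and 6 lower in the knockout. The 1132 genes called down had a median of −0.063 and stood lower (limma, adjusted p = 0.021, and 0.894 with an estimated correlation), with 20 of them higher and 18 lower.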

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

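The tests of the share of Schwann cells, for Fgf5 and for the myelin genes, of the fall in the knockout and of reads shared by Fgf5 were chosen only after the results were seen, and the Fgf5 contrast between time points, the fits on unique reads, the Acta1 term and the choice of genes and response in separate animals were not planned and were added once the data had been seen.

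For 15 of the named genes, out of 26 genes called in all (1 at 1 day and 25 at 14 days), the response to injury differed between the genotypes by a test of the difference itself. At 1 day this was Ecel1 (−5.30, called in 5 of 12 fits that left out 1 library, and lost without wild type sham 7 (adjusted p = 0.106) or 14 (0.144), knockout sham 17 (0.0677) or 6 (0.0632), or transected knockout 15 (0.0754), 17 (0.078) or 6 (0.0748)). Ecel1 lay near 0 reads in wild type sham nerve, so the size of its difference is uncertain. At 14 days, Cspg5 (−4.87), Galnt3 (−4.21) and Cdh10 (−3.06) were called in all 11 such fits. The others were each lost in 4 to 11 of them: Fgf5 (−4.49), Adra2c (−3.85), Epha6 (−3.39), Cpa4 (−3.35), Fabp7 (−3.26), Gfap (−2.68), Fam89a (−2.59), Cdkn2b (−1.63), Akap6 (2.83), Gabre (1.86) and Galnt15 (1.30). The genotype difference of Fgf5 at 14 days was also set against that at 1 day and differed by −4.14 ± 0.40 on the log2 scale (adjusted p = 2.62e-04, 1 of 25 genes called). Calls of the 11 genes that did not hold throughout ended as follows, with adjusted p in brackets. All 11 ended without knockout crush 24 (0.0604 to 0.248), knockout sham 15 (0.0512 to 0.101) or 6 (0.0522 to 0.109), or wild type crush 26 (0.0573 to 0.0984), and all but Akap6 without knockout sham 17 (0.058 to 0.104). Leaving out wild type crush 21 ended those of Adra2c, Cpa4, Epha6, Fam89a, Gabre, Galnt15 and Gfap (0.0514 to 0.0862), wild type crush 23 those of Adra2c, Cdkn2b, Fabp7 and Galnt15 (0.0705 to 0.094), and knockout crush 22 those of Adra2c, Cdkn2b, Epha6, Fam89a and Galnt15 (0.0555 to 0.137). Without wild type sham 7 those of Adra2c, Cdkn2b, Epha6, Fabp7, Fam89a and Galnt15 ended (0.0526 to 0.102), without wild type sham 14 those of Adra2c, Cdkn2b, Cpa4, Fabp7, Gabre, Galnt15 and Gfap (0.0512 to 0.0817), and without wild type sham 1 that of Galnt15 (0.0525). On unique reads Gfap was not called (−2.70, 0.0529).

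Fgf5 was higher in knockout nerve 1 day after transection and lower 14 days after crush. Shared reads do not account for this, since 100% of the exon reads of Fgf5 were uniquely placed, nor does any 1 library, since the adjusted p stayed at or under 0.0082 in all fits that left out 1. A different share of Schwann cells is argued against only as the whole cause. The 26 other Schwann cell genes had a median difference of −0.75 (range −3.12 to 0.45), smaller than the −4.14 of Fgf5 but in the same direction. The 10 other repair genes had a median difference of −1.18, but the repair list did not hold with an estimated correlation at 1 day (adjusted p = 0.322) or 14 days (0.539), and no biological explanation was tested. The kind of injury and the time after it changed together, so which of them matters stays open and was not tested.

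Myelin and cholesterol genes lay lower in knockout nerve 14 days after crush: 20 of 20 were below 0, with a median of −0.65, and 3 were called. Muscle RNA in wild type libraries is a candidate cause, but with Acta1 in the model the median was −0.60 and 19 of 20 were below 0. Of the 20 genes 0 were then called by edgeR, so the single calls depend on that term. A lower share of Schwann cells would raise the markers of all other cells alike. Mural less the mean of fibroblast and macrophage scores was −0.01 (SD 0.19, n = 2) in the knockout and −0.97 (SD 0.27, n = 3) in wild type. The closest libraries were 0.66 apart (for endothelial markers that gap was 0.18, within an SD of 0.37). The other cells thus did not all move alike, but mural cells can differ on their own, so this cannot decide whether the Schwann cell share was lower. A lower share of Schwann cells, a change in the vessel cells and a slower return of myelin in the knockout stay open, with 2 knockout animals.

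Genes higher in knockout sham nerve differed less between genotypes after crush: the 319 genes had median log2 fold changes of 1.66 in sham, 1.01 at 1 day and 0.70 at 14 days. Choosing genes by their sham call would give such a decline by itself, but genes chosen by their call at 14 days had a median in sham that was 0.25 above that at 14 days (2.19 and 1.94). From sham to 14 days the genes chosen at 1 day had medians of 0.35 in wild type (0.50 with genes at 0 reads set at their bound) and −0.45 in the knockout, and the 319 genes 0.25 and −0.52. Sham and 1 day nerves share animals, but choosing genes without an animal and measuring the response from the sham nerve of that animal alone still gave 0.29, 0.47 and 0.31 in wild type (animals 7, 14 and 1) and −0.58, −0.50 and −0.34 in the knockout (animals 15, 17 and 6), or 0.31, 0.51 and 0.39 and −0.57, −0.51 and −0.36 for genes with over 3 reads in that nerve and in the 14 day group. This is consistent with both a rise in wild type and a fall in the knockout, whose sizes overlap between animals and are not ranked here, and a change in the cells of the nerve stays open as a source of either.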

How the results depend on the processing

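The tests on unique reads, with no TMM factor, with Ddx3y or Acta1 as a term, and without animal 1 or the muscle libraries were chosen only after the data were seen. Of 242 named values 209 were called, and 115 of them kept call and sign in every setting, 94 lost the call in at least 1, 13 others gained one and 0 reversed. DESeq2 lost 0 and gained 12, its size factors in edgeR lost 0, no filter lost 6, fits of only the groups compared lost 12, unique reads 5, no TMM factor 2, the Ddx3y term 6, the Acta1 term 23, leaving out animal 1 lost 4 and leaving out the 6 libraries with muscle RNA 85. That last fit had 11 libraries and left 3 groups with 1 library, assumed to vary like the others. Of these groups wild type sham kept only animal 1, which stood apart from the other sham nerves. What that fit lost therefore cannot be put down to muscle RNA alone. The animal as a replicate block changed the 1 day difference in response from 1 call to 2 and no other count by more than 1.5 times, and it changed no call among 67 named values. It kept all list calls and added 1 for transection in wild type, 2 in the knockout and 4 for their difference, all at the preset correlation.

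Counts that moved by more than 1.5 times were as follows, and the cause was not tested. Sham: 167 with the Acta1 term and 168 without the muscle libraries, against 418. Genotypes at 1 day: 75 with only the groups compared and 106 without the muscle libraries, against 231. Genotypes at 14 days: 265 by DESeq2, 228 with only the groups compared, 39 with Acta1, 18 without the muscle libraries, against 129, and leaving out 1 library gave 72, 80 and 77 (wild type crush 23, 21 and 26) and 20 and 64 (knockout crush 22 and 24). Transection in wild type: 760 with only the groups compared, 285 without the muscle libraries, against 2039, with 1299 and 1287 leaving out sham 7 or 14, 1302 leaving out transected 1 and 2707 at most, leaving out sham 1. Transection in the knockout: 1646 with Acta1 and 777 without the muscle libraries, against 2555. Crush in wild type: 310 without the muscle libraries, against 2412. Crush in the knockout: 2783 with only the groups compared, 916 and 1010 leaving out crush 22 or 24 and at most 1427 leaving out sham 6, against 1798.

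For the 1 day difference in response (1 call), DESeq2 gave 20, the replicate block 2, the Ddx3y term, the Acta1 term and the fit without muscle libraries 0 each, and leaving out 1 library 0 (the 7 libraries named with Ecel1) to 6 (wild type sham 1), with 5 and 2 without wild type transected 14 or 1. For the 14 day difference (25), DESeq2 gave 96, only the groups compared 48, Ddx3y 39, leaving out animal 1 58, leaving out the muscle libraries 4, and leaving out 1 library 5 (wild type crush 26, knockout sham 15 or 6, knockout crush 24), 7 (knockout sham 17), 10 (wild type crush 21), 13 or 15 (wild type sham 14 or 7) and at most 33 (wild type sham 1). The overlap of sham and 1 day (163) was 56 with only the groups compared, 94 with Acta1 and 71 without the muscle libraries. That of sham and 14 days (84) was 128 by DESeq2, 27 with Acta1, 14 without the muscle libraries, and leaving out 1 library 16 or 52 (knockout crush 22 or 24), 51, 52 or 53 (wild type crush 23, 21 or 26) and at most 86. That of 1 and 14 days (61) was 37 with only the groups compared, 26 with Acta1, 14 without the muscle libraries and 16 (knockout crush 22) to 59 leaving out 1. Eed at 14 days passed by DESeq2 (−0.48), and the genes down at 1 day did not stand apart at 14 days with an estimated correlation (p = 0.64).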

Other observations

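The intron, neighbour and split tests were set before their own results, so none of the tests of this part was chosen only after its result was seen.

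Other subunits of PRC2 and cell cycle inhibitors also responded to injury. In wild type nerve 14 days after crush, Ezh2, the catalytic subunit of proliferating cells, rose from 12.9 ± 1.72 to 34.5 ± 3 CPM (n = 3 each, log2 fold change 1.42 ± 0.14, edgeR adjusted p = 5.65e-06), while its paralog Ezh1 fell from 140 ± 20.1 to 57.1 ± 1.28 CPM (−1.29 ± 0.13, adjusted p = 5.77e-06). Knockout nerve gave 1.22 for Ezh2 and −0.96 for Ezh1. Of the 5 PRC2 genes tested, 2 rose and 1 fell in either genotype (2 and 1 adjusted over the list alone). In the knockout 1 of the 2 was Eed itself. Its call was lost without knockout sham 15 (edgeR adjusted p = 0.0827) or 17 (0.0584) or knockout crush 24 (0.221). After transection Ezh1 fell in wild type (−0.93) and in the knockout (−1.01). The CDK inhibitor genes Cdkn1a and Cdkn1b fell 14 days after crush in wild type (−1.58 and −1.39) and in the knockout (−1.33 and −1.12, the second lost without knockout animal 22, adjusted p = 0.073). Of 7 such genes 3 rose and 2 fell in wild type and 0 and 2 in the knockout (the same counts adjusted over the list alone). Between genotypes, Epop, a PRC2 cofactor gene, was higher in knockout sham nerve (2.47 ± 0.37, adjusted p = 6.12e-04), 1 of 5 PRC2 genes against 1 lower, Eed (1 and 1 adjusted over the list alone).

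Of 12 extracellular matrix genes, 7 rose and 1 fell 14 days after crush in wild type (7 and 3 adjusted over the list alone), with the collagen genes Col5a1 at 1.14 and Col5a2 at 0.92. In the knockout 3 rose and 1 fell (5 and 1). Col12a1 was higher in knockout sham nerve by 0.83, 1 of the 12 (1 adjusted over the list alone). At 14 days in wild type 2 of 12 macrophage markers rose and 1 fell (1 and 1 adjusted over the list alone), with the microglial and macrophage receptor gene Cx3cr1 at 2.01, 1 of 7 lymphocyte markers rose (1), 2 of 7 fibroblast markers rose (2) and 2 of 6 endothelial markers fell (2), with Cldn5, a tight junction gene, at −1.18. None of the 3 mast cell, 4 mural and 5 adipocyte markers was called there (edgeR; 0 adjusted over the list alone). Of the 4 interferon-stimulated genes 1 rose (2 adjusted over the list alone), and of the 4 skeletal muscle markers 0 were called (0 adjusted over the list alone).

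Intron reads give a second measure of the genes higher in the knockout. Among the 319 genes higher in sham knockout nerve, the 232 with enough intron reads to test had a median log2 fold change of intron reads of 0.97, and 96.6% were above 0, against a median of −0.05 for genes not called. As 232 are 72.7% of the set, the rest is not covered. The genes were chosen by exon reads of the same libraries, so such agreement was likely beforehand. In the other comparisons with intron values, 85.4 to 97.2% of the genes called higher were above 0 as well. More transcription would give this, but a slower decay and a changed share of cells are not excluded.

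Genes called higher were tested for lying within 100 kb of each other. Of the 319 genes higher in sham knockout nerve 35 had such a neighbour, against a median of 26 (5th to 95th percentile 16 to 38) in 10000 random choices of as many tested genes (permutation p = 0.11). Pairs included Cdkn2a with Cdkn2b and En2 with Cnpy1. Of the 907 genes higher 1 day after transection in wild type 242 had one, against 190 (164 to 217, permutation p = 7e-04). The measured genes are those in the table used here, so neighbours outside it were not counted.

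Other splits of the same libraries were fitted for each comparison of 3 against 3. With 10 splits no share under 0.1 can be reached, so they are too few for a test. For knockout against wild type in sham nerve the real split gave 418 genes and the highest other 1, and at 1 day 231 and 0. For 1 day against sham the real split gave 2039 in wild type and 2555 in the knockout, with 511 and 0 as the highest others. Of the 4 splits that part as many pairs, the real one included, all others gave 0 in both genotypes. For 14 days against sham in wild type it was 2412 and 0, and for the 1 day difference in response 1 and 0. In each case only 1 of the splits, the real one, gave as many genes. The other splits mix the real groups, which widens the spread within each. Few calls are therefore likely in them whenever the groups differ.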
